A study of Candida albicans with 6 samples.

How the data were processed

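The series holds RNA sequencing of Candida albicans strain SC5314 in 6 libraries: cells in sorbitol, glucose or GlcNAc (2% each) for 5 h or 24 h, 1 library per group, as the labels give them. No library was left out and none was pooled. Each file held 1 library. It listed, per open reading frame, a gene identifier, a length, a count of unique reads and an RPKM value, per the file headers. The deposited count values were whole numbers that summed exactly to the total printed in each file header. The deposited RPKM values equalled the count divided by the length in kilobases and scaled to the total unique reads, within rounding, as checked from the values. The lengths were taken as coding lengths, since 99.9% of them were multiples of 3. The aligner, its version, the genome build and the strand of the reads are not given in the sources used here, so no coordinates are printed. A gene with near-identical copies may have lost reads to the rule of unique placement. TAR1 lies within the ribosomal DNA, and its reads cannot be told from reads of ribosomal RNA without strand.

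Files listed only genes with at least 1 read, so a gene absent from a file was given a count of 0 there. The 6 files together held 6167 gene identifiers, of which 2787 had a symbol. Names came from the files, the 5 h name first, and 9 identifiers had names that differed between the 5 h and 24 h files. One of these, orf19.781, is printed as DUR31 and was named DUR3 in the 5 h files. Unique reads numbered 10104219, 9283337 and 9958937 in sorbitol, glucose and GlcNAc at 5 h, and 9895778, 9694543 and 9183989 at 24 h. The median tested gene had 810, 646.5 and 669.5 reads at 5 h, and 796, 672 and 554 at 24 h. The 20 most abundant genes took from 8.0% (sorbitol at 24 h) to 15.1% (glucose at 5 h) of the reads.

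The main value was log2 of the ratio of deposited RPKM plus 1 between 2 libraries. Adding 1 understates the ratio of a gene near 0. Genes with a mean of at least 1 RPKM over the 6 libraries were tested, 5956 in all, and those at least 4-fold apart were counted in each direction. Each sugar was compared with each other sugar at the same time (6 comparisons), and 24 h with 5 h in each sugar (3 comparisons). No test across cultures was made, so no p-value is given. Each group has no replicate. A fit of sugar and time over the 6 libraries, which would leave 2 residual degrees of freedom, was not made because it would take the change of the sugar effect with time as error. Counting intervals are exact conditional binomial intervals at 95% on the log2 ratio of read counts scaled to library totals, without the added 1. They cover counting error only. For a gene with 0 reads in 1 library, the ratio is printed as a lower bound from a floor of 3 reads.

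Gene lists numbered 40 and were written before the data were examined, as were the comparisons, the main unit, the filter, the alternatives and the rule for named genes. They were matched on symbols, and 37 had at least 4 tested members. RON1 and NGS1 of the GlcNAc list found no match. For each list the median log2 ratio minus that of the median tested gene was computed, since scaling cannot move this difference. Its percentile was taken among 10000 random lists of the same size matched in 20 bins of mean expression. The random lists could hold the list's own members. A large list that fills much of a few bins, such as the cytosolic ribosomal proteins, is therefore partly compared with itself. A list outside the 2.5 to 97.5 percentiles is said to stand apart, which chance alone gives for 1.9 of 37 lists in a comparison. This describes these libraries only. The percentile assumes independent genes, whereas genes of a list vary together. The lists of alternative oxidases, cell death and chlamydospore genes had fewer than 4 tested members and are given as genes. The 37 others cover GlcNAc catabolism, chitin synthesis, chitinases, central carbon use, sugar, acetate, nitrogen and metal transport, ribosomes, amino acids, cell wall, morphology and mating, stress, proteolysis, signalling, drug efflux, sterols, histones and replication.

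Named genes were chosen by a rule. Among genes with a symbol, at least 10 RPKM and at least 20 reads in the higher library, the 8 highest and the 8 lowest log2 ratios of each sugar comparison were eligible, and the 4 highest and 4 lowest for 24 h against 5 h. All measured members of the GlcNAc list, and the 4 members of each list described with the largest absolute log2 ratio, were eligible too. The members of the 3 small lists, RCT1, and CAT1 or other genes given only as RPKM outside their place in that rule were chosen after their values were seen. A gene that the rule made eligible is not reported here. The overlap of lists at 5 h and 24 h was set against the product of their sizes over the genes tested. The overlap of the comparisons that share the GlcNAc library was also set against 100 simulations of counting noise with no effect.

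The alternatives numbered 9: scaling to the median gene, by TMM or to TPM, added values of 0.1 or 5, no filter or a mean of at least 10 RPKM, scaled counts in place of RPKM, and totals without the 20 most abundant genes. Removal of the trend of log2 ratios with coding length, in 20 length bins (which also sets the median gene to about 0), and random lists matched on length as well were added after the values had been seen. The scripts were tested on simulated data built from the values of 5956 genes. Of genes made to differ by a log2 of 3, 98% passed 4-fold, of genes made to differ by a log2 of 1, 0%, and of genes made not to differ, 0%. Of 200 random lists, 4% lay outside the percentiles, and all 50 lists raised by a log2 of 0.5 lay above them. The simulated genes varied independently and less than the real log2 ratios of GlcNAc against sorbitol at 24 h (standard deviation 1.54). These shares therefore check the scripts and do not carry over to the real lists. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. TMM factors came from edgeR 4.0.16 in R 4.3.3, and edgeR was used for nothing else.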

Results

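RNA was sequenced from cells of Candida albicans, a yeast that lives on people as a commensal and can cause disease. The strain was SC5314, the wild-type reference strain. Stationary-phase cells from rich YPD medium were washed in water and shaken at 30 °C in a medium of 2% sorbitol, 2% glucose or 2% GlcNAc (N-acetylglucosamine, an amino sugar). The 3 sugars and the times of 5 h and 24 h made 6 groups, each with 1 library. Per the study's title, cells die in GlcNAc. Sorbitol, a sugar alcohol, and glucose, the usual carbon source, were the comparison sugars. The median tested gene had 810 unique reads in sorbitol, 646.5 in glucose and 669.5 in GlcNAc at 5 h, and 796, 672 and 554 at 24 h. Between 61 and 90 of the 6167 gene IDs had no read in a library. With 1 library per group, no difference had a replicate check and no test across cultures was made. Ratios were taken on log2 of RPKM plus 1, which understates the ratio of genes near 0. Counting intervals cover counting error only, not the spread between cultures.

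The genes of GlcNAc uptake and catabolism marked both GlcNAc libraries. The GlcNAc transporter gene NGT1 stood at 819.9 RPKM in GlcNAc at 5 h, against 39.5 in sorbitol and 70.5 in glucose, and at 1204, 129 and 119.5 RPKM at 24 h. HXK1, the GlcNAc kinase, was at 4653 RPKM in GlcNAc at 5 h and 3852 at 24 h, and lay between 109.7 and 204 RPKM in the other 4 libraries. DAC1 (the GlcNAc-6-phosphate deacetylase) and NAG1 (the glucosamine-6-phosphate deaminase) reached 3649 and 4565 RPKM in GlcNAc at 5 h, and at most 101 and 114 RPKM without it. GIG1, a gene named for its induction by GlcNAc, was at 468 RPKM at 5 h and 3196 at 24 h in GlcNAc, and at 11.7 RPKM or less in the other 4. HEX1, the secreted N-acetylglucosaminidase, was 4.86-fold higher in GlcNAc than in sorbitol at 5 h (491 against 100.2 RPKM), but at 24 h its log2 ratio was -0.65 (38.1 against 60.5 RPKM). The neighbours by name NAG3, NAG4 and NAG6 did not follow NAG1. NAG3 was at 8.16 RPKM in GlcNAc and 15.6 in sorbitol at 5 h, and NAG4 was under 1 RPKM in both GlcNAc libraries. NAG6 was at 192 RPKM in GlcNAc and 175 in sorbitol at 5 h, and at 48.4 and 113 RPKM at 24 h. Relative to the median gene, the 9 tested genes of the GlcNAc list had a median log2 ratio of 4.55 against sorbitol and 3.54 against glucose at 5 h, and 3.64 and 3.54 at 24 h, above the central 95% of random lists in each. The list was split at 24 h, with 5 of 9 genes above the median gene and 2 (NAG3 and NAG4) at least 4-fold lower against each sugar.

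**Figure D1:**
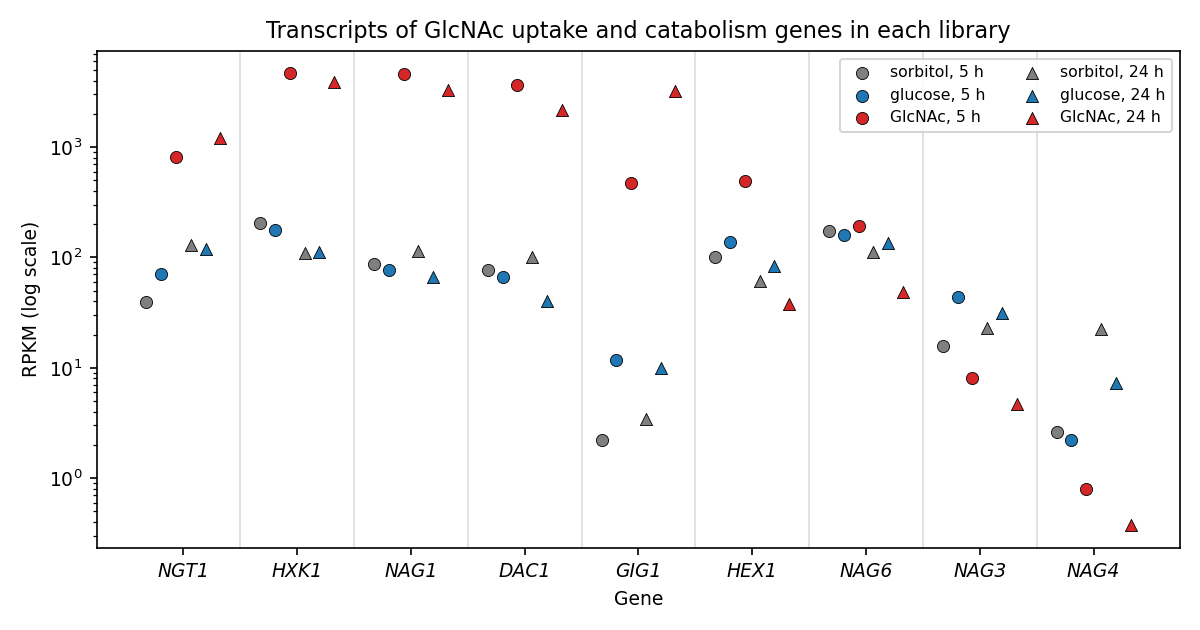
RPKM (log scale) of 9 genes of GlcNAc uptake and catabolism in each of the 6 libraries, circles for 5 h and triangles for 24 h, coloured by sugar, 1 point per library. NGT1, HXK1, NAG1, DAC1 and GIG1 lie higher in both GlcNAc libraries than in the other 4, as with NGT1 at 819.9 and 1204 RPKM, whereas HEX1 does so only at 5 h.

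GlcNAc against sorbitol at 5 h compared the early library in the amino sugar with that in the non-fermented sugar alcohol. Besides the GlcNAc genes, GlcNAc cells held far more PHO89 (a sodium-phosphate symporter, 472-fold higher, 2025 against 3.29 RPKM, counting interval of log2 8.90 to 9.65) and more GIT2, of the glycerophosphodiester transporter family (41.7-fold). The adhesin ALS1 was 129-fold higher (1869 against 13.4 RPKM). The amino acid permeases GAP1 and GAP6 were 52.8-fold and 23.6-fold higher, and MET3, the ATP sulfurylase of sulfate assimilation, was 48.1-fold higher. The urea and polyamine transporter gene DUR31 was 56.1-fold lower (7.19 against 458 RPKM, log2 -6.23 to -5.77), the urea amidolyase gene DUR1,2 38.0-fold and the sugar transporter gene HGT19 38.6-fold. The carboxylic acid transporter genes JEN2 and JEN1 were 31.8-fold and 29.6-fold lower, the oligopeptide transporter gene OPT3 21.3-fold, and the glutathione S-transferase gene GST3 and DAL52 24.4-fold and 21.8-fold.

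Among 5956 genes tested, 133 were at least 4-fold higher in GlcNAc than in sorbitol at 5 h and 110 at least 4-fold lower. With the median gene set to 0 the counts were 150 and 91, and with TPM 125 and 127. The median gene lay at a log2 ratio of -0.21, so each list median in this text is relative to the median gene of its comparison. Each has a percentile among 10000 random lists matched on expression, where 100 or 0 means that no random list lay beyond it. Genes of respiration stood above the median gene: all 18 of the TCA cycle (median 0.55, percentile 99.5), with citrate synthase CIT1 2.64-fold higher. So did 33 of 35 of the respiratory chain and ATP synthase (median 0.69, percentile 100). The alternative oxidase genes AOX1 and AOX2 were 6.83-fold and 5.37-fold higher. Amino acid synthesis genes stood higher as well (60 of 65 above the median gene, median 0.68, percentile 100), led after MET3 by MET15 (8.45-fold), MET14 (7.83-fold) and CYS3 (6.35-fold). Higher too were the ribosomal proteins of the cytosol (median 0.54, percentile 99.4) and of mitochondria (median 0.57, percentile 100). The opaque-cell list was higher by its median (median 0.86, percentile 99.8) but split, with 5 of 8 above the median gene. In it WOR3 was 17.4-fold higher and OP4 2.42-fold lower, and SAP3 had 1 read against 167 (log2 -12.68 to -4.87). Higher by their medians were also the glycerol and osmolyte genes (median 0.51, percentile 97.8, with the sodium pump gene ENA2 5.66-fold higher and GCY1 7.72-fold lower) and the iron and copper genes (median 0.55, percentile 99.98). Of the last, the haem-binding surface protein gene RBT5 was 19.8-fold higher and the siderophore transporter gene SIT1 8.86-fold, whereas the multicopper oxidase gene FET99 was 15.7-fold lower. The 4 chitinase genes had a relative median of 1.03 (percentile 99.7), with CHT2 and CHT3 3.55-fold and 2.71-fold higher and CHT1 2.44-fold lower.

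Genes of fatty acid use stood lower at 5 h. Of the beta-oxidation and carnitine genes, 15 of 18 lay below the median gene (median -1.04, percentile 0), among them the acyl-CoA oxidase gene PXP2 (7.02-fold lower), FOX2 (6.11-fold), FAA2-3 (5.20-fold) and POX1-3 (3.86-fold). Ribosome biogenesis genes were lower (50 of 54 below the median gene, median -0.64, percentile 0), as with DBP7, NOP14 and MAK21, at 2.67-fold, 2.56-fold and 2.42-fold. The list of ammonium, urea and amino acid use was lower by its median (median -0.51, percentile 0) but held 3 genes at least 4-fold higher beside 8 at least 4-fold lower. Hexose transporters (median -0.52, percentile 0.06) and vacuolar proteases (median -0.51, percentile 0.34) were lower. Acetate and aldehyde genes (median -0.56, percentile 0.09), glycolysis (median -0.25, percentile 0.01) and DNA replication genes (median -0.21, percentile 1.70) were lower too, the last inside the range of random lists matched on length (percentile 5.06). The ATO family, membrane proteins tied to acetate and ammonium export, had a relative median of -0.80 (percentile 0.19) but a mean of -0.03, since ATO6 and ATO1 were 11.3-fold and 4.09-fold higher. Single genes of other lists stood out. Higher were the peptide toxin gene ECE1 (40.2-fold) and the cell wall glycosidase gene PHR1 (14.1-fold) of the hypha-associated list, the surface superoxide dismutase gene SOD5 (28.0-fold), and the heat shock genes HSP30 (28.5-fold) and HSP21 (11.4-fold). Lower were the catalase gene CAT1 (8.11-fold), the acid trehalase gene ATC1 (4.90-fold) and the yeast-form wall protein gene YWP1 (15.6-fold). Of 37 lists with at least 4 tested members, 10 stood above and 9 below the central 95% of random lists. Chance gives 1.9, and genes of a list are not independent.

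GlcNAc against glucose at 5 h set the amino sugar against the preferred sugar. PHO89 (516-fold higher), ALS1 (97.4-fold), GIT2 (94.6-fold), MET3 (70.5-fold), NAG1 (58.8-fold), SOD5 (57.8-fold), DAC1 (54.1-fold) and PGA34, a putative GPI-anchored protein gene (42.2-fold), were the highest named genes. Against glucose the lowest were again DUR31 (57.9-fold, 7.19 against 473 RPKM) and DUR1,2 (16.6-fold), joined by the putative drug transporter gene QDR1 (34.5-fold), the mannosyltransferase gene MNN22 (27.8-fold), XUT1 (23.2-fold), AMO1 (16.9-fold), ZCF19 (17.6-fold) and the sugar transporter gene HGT7. HGT7 stood at 10378 RPKM in glucose, 538 in GlcNAc and 828 in sorbitol.

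In this comparison 172 genes were at least 4-fold higher in GlcNAc and 120 at least 4-fold lower, and the median gene lay at -0.02. All 18 glycolysis and fermentation genes lay below it (median -1.20, percentile 0), with pyruvate decarboxylase PDC11 6.62-fold, the regulator TYE7 4.46-fold and hexokinase HXK2 4.40-fold lower. Trehalose and glycogen (median -0.54, percentile 0.37), vacuolar proteases (median -0.64, percentile 0.23), ribosome biogenesis (median -0.45, percentile 0) and nitrogen use (median -0.44, percentile 0.02) stood lower too. Within the last list the glutamate dehydrogenase gene GDH2 was 14.2-fold higher. Higher were the iron and copper genes (median 0.76, percentile 100), with RBT5 24.9-fold, SIT1 14.1-fold and FET3 13.3-fold. Chaperones were higher (20 of 23 above the median gene, median 0.73, percentile 100), with HSP30 32.0-fold and HSP31 6.39-fold. The TCA cycle (median 0.53, percentile 99.8, CIT1 4.21-fold) and the respiratory chain (median 0.53, percentile 99.96) stood higher. So did gluconeogenesis and the glyoxylate cycle (median 0.51, percentile 98.8, ACS2 4.13-fold) and oxidative stress defence (median 0.47, percentile 99.8), and AOX1 was 10.9-fold higher. Amino acid synthesis (median 0.39, percentile 100), DNA replication (median 0.29, percentile 99.7, MCM6 2.90-fold), chitinases (median 0.68, percentile 97.9, CHT2 17.1-fold) and the opaque-cell list (median 0.71, percentile 99.1) also stood higher. So did the GPI-anchored and cell wall proteins (median 0.26, percentile 98.5, PHR1 23.4-fold, RHD3 14.7-fold) and the mitochondrial ribosomal proteins (median 0.24, percentile 98.0). These 2 lists lay at percentiles of 97.0 and 92.5 once random lists were matched on coding length. The lists of hexose transporters and beta-oxidation did not stand apart from random lists (median 0.03, percentile 56.3, and median 0.22, percentile 95.0), yet HGT2 and HGT1 were 23.5-fold and 11.3-fold higher.

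Glucose against sorbitol at 5 h compared a fermentable sugar with the sugar alcohol, without GlcNAc. Glucose cells had more HGT7 (12.5-fold), QDR1 (26.7-fold), HXK2 (5.37-fold), the glycerol-3-phosphatase gene RHR2 (5.54-fold), the serine and threonine dehydratase gene CHA1 (10.3-fold), RAS2 (7.48-fold) and GAP6 (5.54-fold). All 18 glycolysis and fermentation genes lay above the median gene (median 1.05, percentile 100), with PDC11 and alcohol dehydrogenase ADH1 4.09-fold and 3.26-fold higher. The GlcNAc genes as a list did not stand apart (median 0.02, percentile 43.8). Fewer genes differed than with GlcNAc: 34 were at least 4-fold higher and 96 at least 4-fold lower in glucose, with the median gene at -0.15.

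Among the lowest genes in glucose at 5 h, the transcription factor gene TRY4 had 2 reads, against 1463 in sorbitol (counting interval of the log2 read ratio -12.44 to -7.54), and SCW4, a cell wall protein gene, had 2 and 590 reads (-11.13 to -6.22). PXP2 was 71.6-fold lower, the opaque-phase gene OP4 69.5-fold, HGT19 38.9-fold, the formate dehydrogenase gene FDH1 36.0-fold, JEN2 33.1-fold and HGT17 25.5-fold. Beta-oxidation and carnitine genes (17 of 18 below the median gene, median -1.71, percentile 0), acetate and aldehyde genes (median -1.30, percentile 0), gluconeogenesis (median -0.56, percentile 0.07, ICL1 4.21-fold) and hexose transporters (median -0.41, percentile 0.17) were lower. So were DNA replication genes (median -0.61, percentile 0, with CDC46 and MCM6 5.48-fold and 5.45-fold), chaperones (median -0.36, percentile 0.01, SSA2 4.71-fold), ribosome biogenesis (median -0.21, percentile 0.08) and histones (median -0.27, percentile 1.10). Oxidative stress defence was lower by its median (median -0.25, percentile 0.98, mean -0.02), where CAT1 was 3.83-fold lower but SOD1 3.78-fold higher. Cytosolic (median 0.41, percentile 99.98) and mitochondrial ribosomal proteins (median 0.27, percentile 99.3) were higher in glucose. So were amino acid synthesis (median 0.23, percentile 99.98) and trehalose and glycogen genes (median 0.46, percentile 99.4, GSY1 2.39-fold). With genes under a mean of 10 RPKM left out, the hexose transporters were at a relative median of 0.01.

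GlcNAc against sorbitol at 24 h covered the later state. PHO89 was 1042-fold higher (2677 against 1.57 RPKM, log2 10.21 to 11.33), and GIG1 (721-fold), SOD5 (424-fold), ALS1 (282-fold), RBT5 (272-fold), the lipid translocation gene RTA2 (163-fold) and MET3 (120.5-fold) followed. PBR1 had 1089 reads in GlcNAc and 2 in sorbitol (log2 7.34 to 12.24). RCT1 had the most reads of any gene in GlcNAc at 24 h (80269), where TDH3 led the other 5 libraries. The lowest were the sugar transporter genes HGT17 (589-fold, 2.61 against 2122 RPKM), HGT19 (297-fold) and HGT7 (146-fold), YWP1 (350.2-fold), DUR31 (296-fold), OPT3 (189-fold), FDH1 (98.3-fold) and the ammonium permease gene MEP1 (91.7-fold).

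At 24 h 27 of 75 cytosolic ribosomal protein genes were at least 4-fold higher in GlcNAc and 74 lay above the median gene (median 2.26, percentile 100). RPL40B was 6.94-fold higher, RPL35 6.54-fold and RPL15A 6.47-fold. These genes are short, with a median coding length of 450 bases against 1242 for all tested genes. Short genes lay relatively higher in GlcNAc, with medians of -0.08 in the shortest and -0.89 in the longest of 6 equal parts. Amino acid synthesis genes were likewise high (24 of 65 at least 4-fold higher, median 1.90, percentile 100), led by MET3, LYS22 (29.1-fold), CYS3 (20.3-fold) and LEU4 (15.2-fold). The wall and its sugars were represented by all 12 genes of UDP-GlcNAc and chitin synthesis above the median gene (median 1.32, percentile 99.96), with the chitin synthase gene CHS2 9.42-fold and GFA1 7.22-fold. CHS2 stood at 290 RPKM in GlcNAc, 29.9 in sorbitol and 113 in glucose, and GFA1 at 641, 87.9 and 693 RPKM. Chitinases (median 1.24, percentile 98.1) and GPI-anchored and wall proteins (median 0.93, percentile 99.96) stood higher too, with PGA23 and PGA1 31.6-fold and 21.5-fold. Hypha-associated genes were higher (15 of 17 above the median gene, median 1.45, percentile 99.6). ECE1 had 198 reads against 0 and was at least 71.1-fold higher by a floor of 3 reads. PHR1 was 24.9-fold and IHD1 11.7-fold higher, and FAV2 was 46.4-fold lower. Mitochondrial ribosomal proteins stood higher too (median 1.15, percentile 99.99), whereas the respiratory chain did not stand apart (median -0.03, percentile 18.2). Iron and copper genes stood apart only among random lists matched on length (median 0.49, percentile 97.6 in place of 94.3).

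Genes of glycolysis and of fatty acid use were lower in GlcNAc than in sorbitol at 24 h. Of the glycolysis and fermentation genes, 11 of 18 were at least 4-fold lower (median -1.81, percentile 0), with PGK1 13.9-fold, PFK2 9.04-fold and pyruvate kinase CDC19 7.32-fold. Of the beta-oxidation and carnitine genes, 12 of 18 were at least 4-fold lower (median -1.98, percentile 0), with PXP2 50.7-fold and FOX2 19.2-fold. Of the nitrogen genes 13 of 26 were so (median -1.63, percentile 0), with DUR1,2 86.0-fold. Chaperones (median -1.32, percentile 0, HSP30 21.1-fold, ASR2 13.7-fold) and acetate and aldehyde genes (median -1.55, percentile 0.01, ALD6 20.9-fold) were lower. So were vacuolar proteases (median -1.11, percentile 0.43, CPY1 5.00-fold), trehalose and glycogen (median -1.03, percentile 0.36, ATC1 6.61-fold) and hexose transporters (median -0.86, percentile 0.20). The TCA cycle was lower by its median (median -0.63, percentile 1.09) but split, with a mean of -0.14 and 5 of 18 genes above the median gene. Gluconeogenesis and the glyoxylate cycle did not stand apart (median 0.01, percentile 49.5), with ICL1 6.67-fold higher. Ribosome biogenesis was lower (45 of 54 below the median gene, median -0.46, percentile 1.42 among lists matched on length too), and the 4 autophagy genes were lower (median -1.11, percentile 2.07) but inside the range of random lists matched on length (percentile 4.75). The ATO family split, with ATO1 21.9-fold higher and ATO2 33.6-fold lower (median -1.53, mean -0.62, percentile 0.11). CAT1 was far lower in GlcNAc than in sorbitol (24.0 against 1599 RPKM). Of the 5956 genes, 385 were at least 4-fold higher and 463 at least 4-fold lower, so 45.4% of these were higher, with the median gene at -0.43. That split depends on scaling: 66.3% were higher with the median gene set to 0 (548 and 278 genes), 63.5% with TMM scaling (520 and 299), 63% with the length trend removed, which also sets the median gene to 0 (500 and 294), and 27.8% with TPM (289 and 750).

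**Figure D2:**
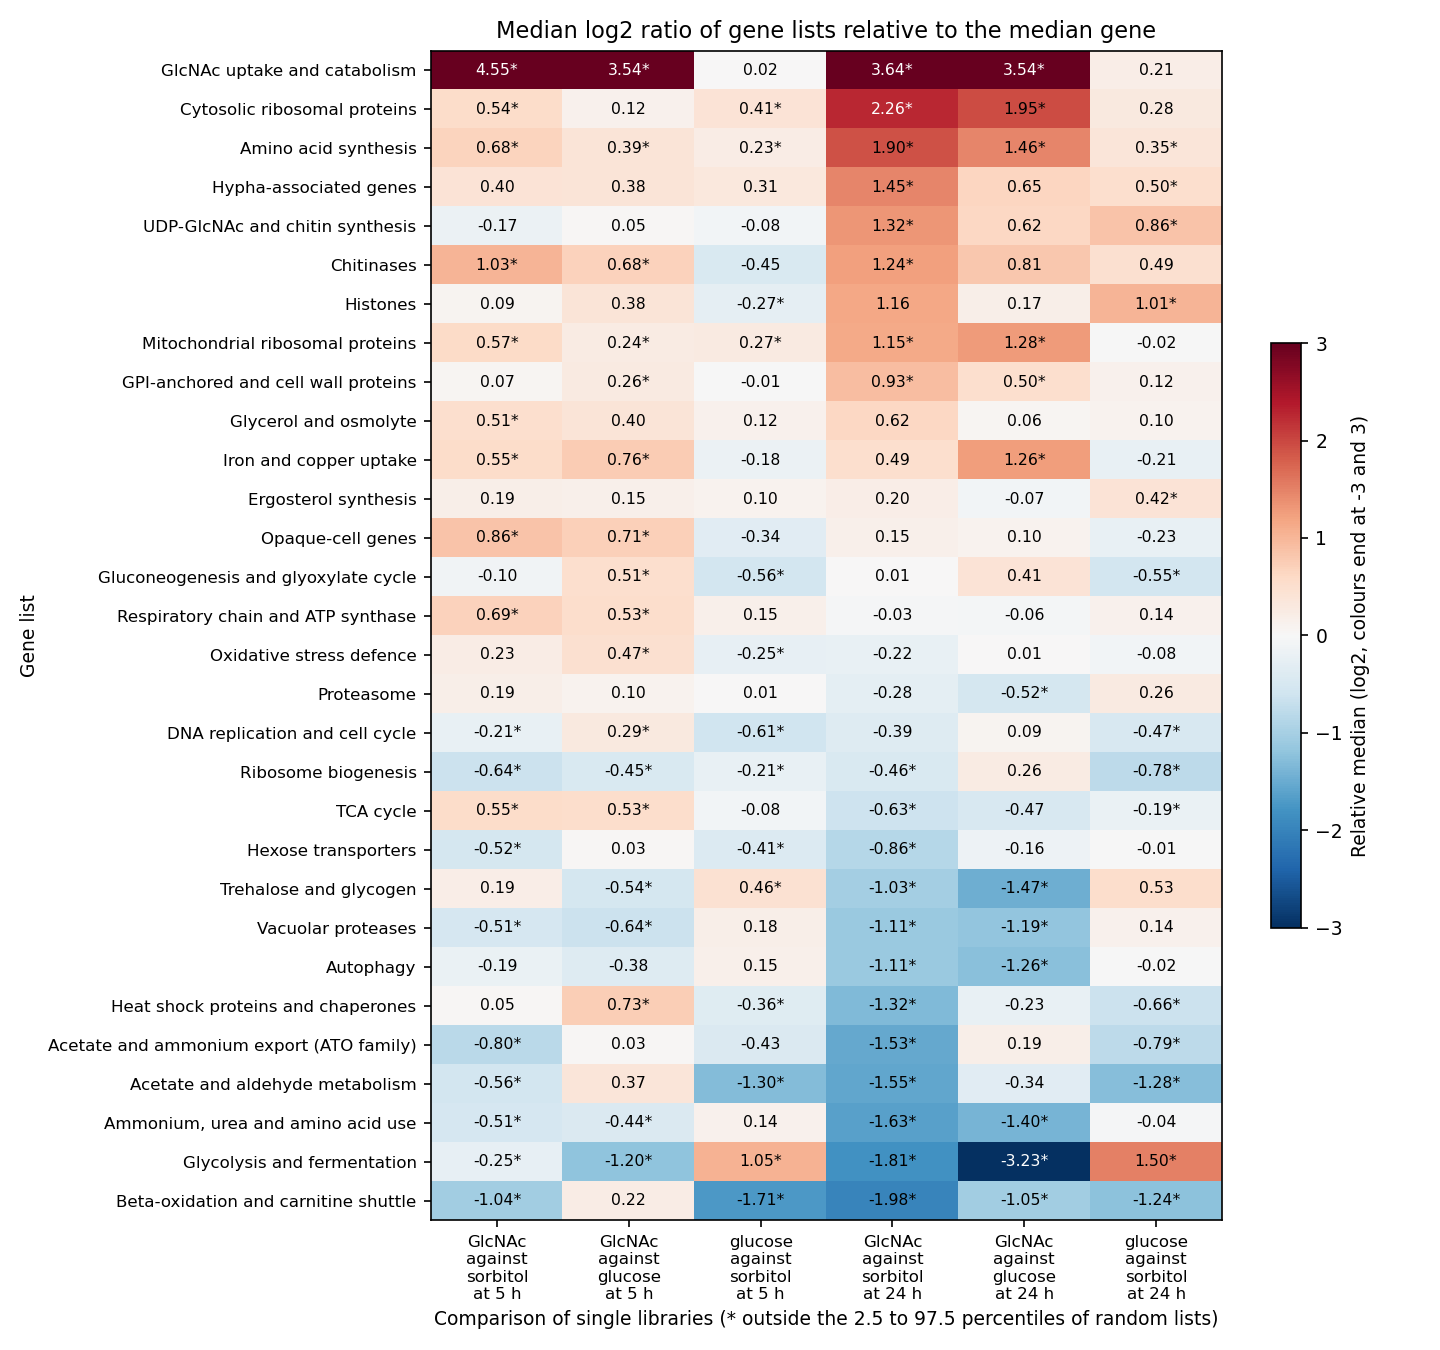
Median log2 ratio of each gene list minus the median gene of the comparison, for the 30 lists that stood outside the central 95% of random lists in at least 1 of the 6 sugar comparisons (cells with an asterisk), 1 library per group. Glycolysis and fermentation lies at -3.23 in GlcNAc against glucose at 24 h and at 1.05 in glucose against sorbitol at 5 h, and cytosolic ribosomal proteins reach 2.26 in GlcNAc against sorbitol at 24 h.

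GlcNAc against glucose at 24 h had the lowest glycolysis median of the 9 comparisons. HGT7 was 1354-fold lower in GlcNAc (2.52 against 4769 RPKM, log2 -11.38 to -10.43), and 16 of 18 glycolysis and fermentation genes were at least 4-fold lower (median -3.23, percentile 0), with PFK2 26.2-fold, PGK1 24.3-fold, PDC11 22.5-fold and PFK1 21.6-fold. The hexose transporters as a list did not stand apart (median -0.16, percentile 24.9). Highest were PHO89 (655-fold), RBT5 (465-fold), ALS1 (409-fold), GIG1 (291-fold), GIT2 (273-fold), RTA2 (159-fold) and MRV2 (136-fold). SOD5 had 8187 reads in GlcNAc against 2 in glucose (log2 10.22 to 15.12). Lowest beside HGT7 were DUR31 (278-fold), OPT3 and OPT2 (136-fold and 51.2-fold), MEP1 (72.3-fold), the methyltransferase gene CRG1 (51.3-fold), and DUR1,2 (49.8-fold). The amino acid permease gene GAP2 had 2 reads against 1053 (log2 -12.01 to -7.11).

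Ribosomal protein genes were higher than in glucose too, in the cytosol (23 of 75 at least 4-fold, median 1.95, percentile 100, RPL30 6.85-fold) and in mitochondria (median 1.28, percentile 100, MRPL37 6.95-fold). Higher as well were amino acid synthesis (18 of 65 at least 4-fold, median 1.46, percentile 100, LYS22 17.9-fold, HIS3 15.3-fold) and iron and copper genes (9 of 25 at least 4-fold, median 1.26, percentile 99.99). The iron genes included CSA1 (17.6-fold) and PGA7 (17.5-fold), which with RBT5 encode haem-binding proteins, and the putative ferric reductase gene CFL5 (23.8-fold). GPI-anchored and wall proteins were higher (median 0.502, percentile 98.4) but inside the range of random lists matched on length (percentile 97.3). Such matching put 3 more lists apart as higher: UDP-GlcNAc and chitin synthesis (median 0.62, percentile 98.8 in place of 97.0), ribosome biogenesis (0.26, 98.8 in place of 96.1) and hypha-associated genes (0.65, 97.8 in place of 92.7). Lower were trehalose and glycogen (median -1.47, percentile 0.01, TPS2 8.71-fold), nitrogen use (median -1.40, percentile 0) and vacuolar proteases (median -1.19, percentile 0.43, PRB1 6.37-fold). So were autophagy (median -1.26, percentile 0.85, ATG9 4.03-fold), beta-oxidation (median -1.05, percentile 0, PXA1 6.11-fold) and the proteasome (median -0.52, percentile 2.41). The TCA cycle did not stand apart (median -0.47, percentile 7.65): MDH1 was 4.61-fold higher and IDH1 3.32-fold lower. Chaperones, lower than in sorbitol at this time, did not stand apart from glucose (median -0.23, percentile 24.8). In all, 343 genes were at least 4-fold higher and 319 at least 4-fold lower (51.8% higher), with the median gene at -0.22. The share higher was 62.2% with the median gene set to 0 (414 and 252) and 37.6% with TPM (272 and 452).

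Glucose against sorbitol at 24 h again set genes of fermentation apart from genes of fat use. MET3 (42.9-fold), QDR1 (26.3-fold), the wall protein gene PIR1 (19.9-fold, 3666 against 183 RPKM), the sterol oxidase gene ERG251 (15.3-fold), UGA4 (10.7-fold), HOL1 (10.4-fold), HXK2 (9.64-fold) and HGT7 (9.31-fold) were highest in glucose. TRY4 (103-fold), HSP30 (64.0-fold), CFL5 (43.8-fold), FDH1 (37.5-fold), FET3 (32.5-fold), PXP2 (21.5-fold), HGT17 (17.0-fold) and the carnitine acetyltransferase gene CTN3 (15.9-fold) were lowest. Glycolysis and fermentation stood higher (17 of 18 above the median gene, percentile 100, PDC11 7.57-fold), and so did histones (median 1.01, percentile 98.9, HHF22 3.94-fold). Higher too were UDP-GlcNAc and chitin synthesis (median 0.86, percentile 99.9, GFA1 7.80-fold), hypha-associated genes (median 0.499, percentile 98.2, HGC1 6.01-fold), ergosterol synthesis (median 0.42, percentile 99.7) and amino acid synthesis (median 0.35, percentile 99.9). Beta-oxidation (median -1.24, percentile 0), acetate and aldehyde metabolism (median -1.28, percentile 0), and the ATO family (median -0.79, percentile 0.88) were lower. So were ribosome biogenesis (median -0.78, percentile 0), chaperones (median -0.66, percentile 0), gluconeogenesis (median -0.55, percentile 0.87) and DNA replication (median -0.47, percentile 0.01, CDC46 7.20-fold). The TCA cycle was marginally lower (median -0.19, percentile 2.43), and lay inside the range of random lists matched on length (percentile 3.61). Here 89 genes were at least 4-fold higher and 114 at least 4-fold lower, with the median gene at -0.17. Higher genes were the more numerous with the median gene set to 0 (110 and 95) or TMM scaling (108 and 95), but not with TPM (81 and 139).

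The 5 h and 24 h lists shared genes. Of the genes at least 4-fold higher in GlcNAc than in sorbitol, 84 were so at both times, where independent lists of the same sizes would share 8.6, and 82 were lower at both times (8.55). Against glucose 89 genes were higher (9.91) and 82 lower at both times (6.43), and for glucose against sorbitol the counts were 20 (0.51) and 50 (1.84). The genes higher in glucose than in sorbitol at both times included HGT7, HXK2, PDC11, QDR1, GAP6, CRG1, WOR3 and PGA57. GlcNAc stood apart from both other sugars for 105 higher and 60 lower genes at 5 h, where counting noise alone with no effect gave 0.01 and 0.01 and independent lists would share 3.84 and 2.22. At 24 h it did so for 254 higher and 212 lower genes, where noise alone gave 0.03 and 0.04 and independent lists would share 22.2 and 24.8. Part of that excess may come from the GlcNAc library that both comparisons share, which as a single library could not be split. The simulations held counting error only, without spread between cultures, so they had little room to give values far from 0.

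**Figure D3:**
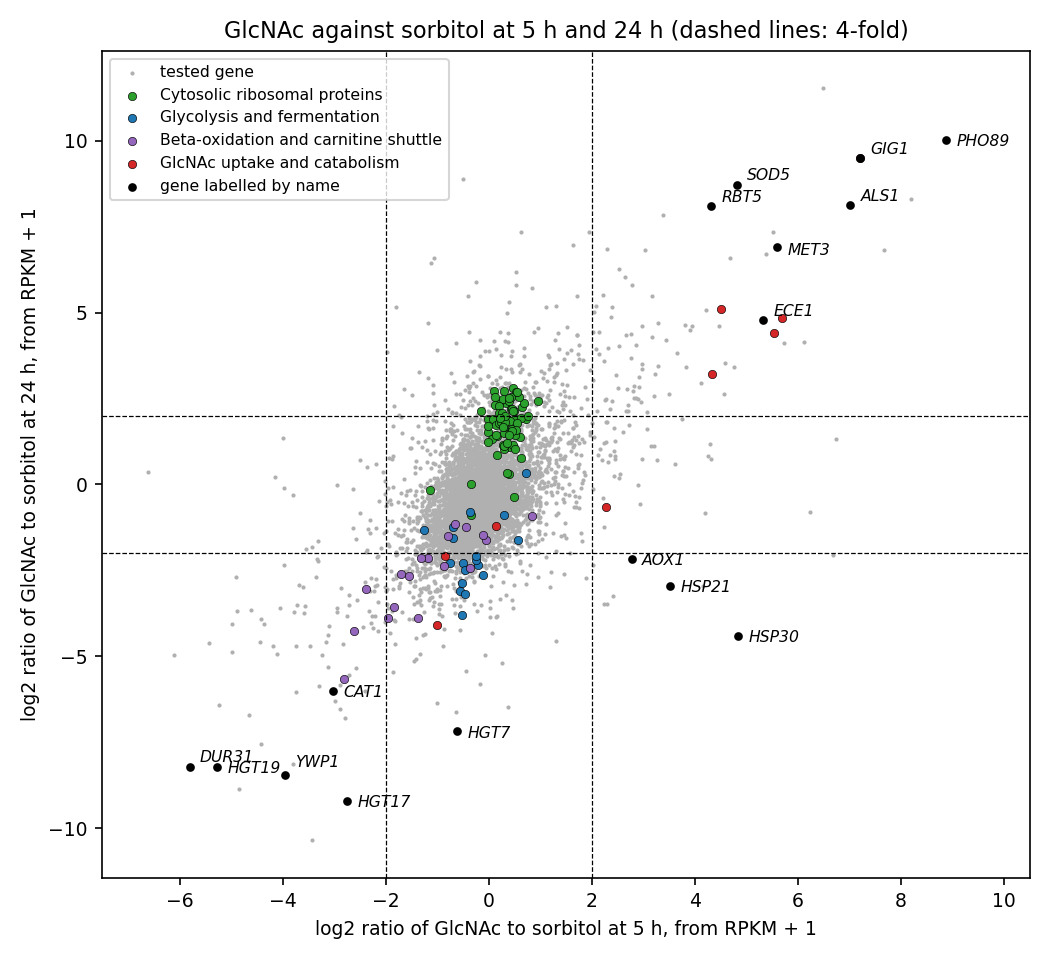
Log2 ratio of GlcNAc to sorbitol from RPKM plus 1 at 5 h (horizontal axis) and 24 h (vertical axis) for the 5956 tested genes, with 4 gene lists in colour and selected genes labelled by name, dashed lines at 4-fold. PHO89 lies at 8.88 and 10.03, DUR31 at -5.81 and -8.21, and HSP30 at 4.83 and -4.40.

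The same sugars at 24 h against 5 h gave values that mix time and batch. The 5 h and 24 h libraries came in separate sets of tables, so time and batch cannot be told apart. In sorbitol HSP30 (41.3-fold), the peroxiredoxin gene PRX1 (28.2-fold), CFL5 (13.5-fold) and BTA1 (12.8-fold) were highest at 24 h. The histone H3 genes HHT2 (35.1-fold) and HHT21 (30.8-fold), PGA6 (27.7-fold) and PGA13 (25.8-fold) were lowest. In glucose PRX1 (139-fold), MET3 (44.9-fold), TAR1 (29.8-fold) and MET14 (17.4-fold) were highest. RBT5 (20.2-fold), PHO87 (19.0-fold), CHT3 (16.4-fold) and CRH11 (11.7-fold) were lowest. In GlcNAc GIT4 (36.2-fold), MRV3 (32.9-fold), the ribosome biogenesis gene MAK16 (21.6-fold) and PRX1 (20.4-fold) were highest. HGT7 (153-fold), RBE1 (100.1-fold) and AOX1 (28.5-fold) were lowest. PGA26 had 0 reads against 104 (at least 32-fold lower). Ribosome biogenesis genes were higher at 24 h in sorbitol (median 1.17, percentile 100), glucose (median 0.60, percentile 100) and GlcNAc (median 1.21, percentile 100). Histones (-2.60, -1.59 and -1.78), chitinases (-2.89, -2.12 and -2.94), DNA replication genes (-0.74, -0.64 and -0.997) and GPI-anchored and wall proteins (-1.27, -1.03 and -0.55) had lower relative medians at 24 h in sorbitol, glucose and GlcNAc, all below the central 95% of random lists. So had the hypha-associated genes (-0.72, -0.60 and -0.77, percentiles 0.71, 1.08 and 1.88). In GlcNAc these lay just inside the range of random lists matched on length (percentile 2.53). In GlcNAc alone of the 3 sugars did glycolysis have 12 of 18 genes at least 4-fold lower (median -2.17, percentile 0) and cytosolic ribosomal proteins 18 of 75 at least 4-fold higher (median 1.75, percentile 100). Glycolysis was also lower by its median in sorbitol (median -0.75, percentile 1.30), but inside the range of random lists matched on length (percentile 3.06). UDP-GlcNAc and chitin synthesis genes were lower at 24 h in sorbitol (median -0.95, percentile 0.06). They did not stand apart in glucose (median -0.09, percentile 26.9) or in GlcNAc (median 0.42, percentile 85.1). At least 4-fold higher and lower genes numbered 106 and 179 in sorbitol, 70 and 98 in glucose, and 303 and 383 in GlcNAc, with median genes at 0.001, -0.002 and -0.23. In GlcNAc 44.2% of these were higher, against 60.5% with the median gene set to 0 (411 and 268), 56.4% with TMM scaling (387 and 299) and 58.7% with the length trend removed, which also sets the median gene to 0 (399 and 281). With TPM the share was 35.6% (254 and 459).

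Of the 37 lists, 7 did not stand apart in any of the 6 sugar comparisons: the ALS adhesins (percentiles from 8.53 to 90.37), drug efflux pumps (19.23 to 82.77), meiosis and mating (14.04 to 89.08), Ras-cAMP-PKA signalling (13.57 to 79.61), secreted aspartyl proteases (14.11 to 88.98), sorbitol and pentitol metabolism (4.87 to 94.17) and white-cell genes (7.66 to 49.85). With random lists matched on length, the ALS adhesins stood higher in GlcNAc against sorbitol at 5 h (percentile 98.2). Among 3 tested genes tied to cell death, the metacaspase gene MCA1 was at 386 RPKM in GlcNAc at 24 h, 99.5 in sorbitol and 137 in glucose, and at 162, 212 and 172 RPKM at 5 h. NMA111 and DNM1 were at 36.0 and 61.0 RPKM in GlcNAc at 24 h and 62.2 and 128 in sorbitol. Of the alternative oxidase genes at 24 h, AOX2 was at 1187 RPKM in GlcNAc and 1006 in sorbitol, and AOX1 at 20.9 and 97.0. CSP37, the most abundant of 3 chlamydospore-associated genes, was at 778 RPKM in GlcNAc, 1440.3 in sorbitol and 855 in glucose at 24 h, while CSP1 and CSP2 stayed at 32.6 RPKM or less in all 6 libraries.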

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

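Of the tests below, the length test of the ribosomal proteins was set out before it was run, and the others were chosen after the result had been seen.

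Gene lists that stood apart at both times, and named genes at least 4-fold apart at both times, were searched for opposite directions at 5 h and 24 h. GlcNAc against sorbitol had 1 such list and 4 such genes, and glucose against sorbitol 1 such list. Other lists and genes that changed side did not pass both limits. These differences between times were not tested, since each group had 1 library, and time and batch cannot be told apart. The TCA cycle had a relative median of 0.55 at 5 h and -0.63 at 24 h, a difference of -1.18. All 18 genes lay above the median gene at 5 h. At 24 h the list was split, with 5 of 18 still above it and a relative mean of -0.14. HSP30 had log2 ratios of 4.83 at 5 h and -4.40 at 24 h (difference -9.23), HSP21 3.52 and -2.95 (difference -6.46), HSP31 2.30 and -3.49 (difference -5.79) and AOX1 2.77 and -2.16 (difference -4.93). HSP30, HSP21, HSP31 and AOX1 were among 9 genes at least 4-fold higher at 5 h and at least 4-fold lower at 24 h in that comparison, where independent lists of the same sizes would share 10.3. The HSP30 difference does not lie in GlcNAc alone, since HSP30 was also higher at 24 h than at 5 h in sorbitol. As a list, chaperones at 24 h against 5 h were higher in sorbitol (relative median 0.84, percentile 99.99) and lower in GlcNAc (-0.94, percentile 0.22). The histones in glucose against sorbitol had a relative median of -0.27 at 5 h and 1.01 at 24 h, a difference of 1.28.

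For the TCA cycle, 1 technical explanation was tested. Coding length bias does not account for it, since -1.18 of the difference was left once the length trend was removed. That test had little room to give another outcome: the list's median coding length was 1357.5 bases, near the 1242 of all tested genes. The list at 24 h against 5 h had a relative median of -1.42 in GlcNAc (percentile 0.03), against -0.36 in sorbitol and -0.35 in glucose, which places most of the difference in the GlcNAc libraries. A technical effect on the GlcNAc library of 1 time alone was not tested and stays open.

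The cytosolic ribosomal proteins stood well above the median gene in GlcNAc at 24 h, and they are short, in libraries where short genes lay higher. Coding length bias would put the list within the range of length-matched random lists or remove most of its value. Against both other sugars the relative median was at least 1.85 without the length trend, and the length-matched percentile was 100. A length trend shared by all genes is thus not the main source of the value. Removing the trend had little room to give another outcome. Against sorbitol the shortest of 6 equal parts lay at -0.08, where the median gene lay at -0.43. Poorer RNA in that library cannot be told apart from the sugar. The median share of a gene covered by reads was 93.1% there and 91.9% to 94.1% in the other 5, but this measure is near its ceiling in every library and decides nothing.

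Histones were lower, and TAR1 higher, at 24 h than at 5 h in all 3 sugars. TAR1 took from 0.012% to 0.021% of the reads at 5 h and from 0.23% to 0.348% at 24 h. A difference between the 5 h and 24 h sets in library making or sequencing cannot be told apart from time, and the smallest of the 3 histone differences was -1.59.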

How the results depend on the processing

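The length trend and the length-matched random lists were chosen after seeing the data, and the 9 other alternatives before. Counts of genes at least 4-fold apart stayed within 1.5 times the main count in 173 of 180 cases. In 3296 cases a list median shifted no further than the middle of its interval lies from its end, and further in 14. In 2 cases the median of a list that stood apart changed sign, and sign changes of other lists were not counted. Scaling to the median gene, by TMM or to TPM and scaled counts hardly move a relative median by construction. Their agreement, in 333 cases each, is therefore no check. Log2 ratios of named genes, judged likewise by their counting interval, stayed in 11464 cases and moved in 3079. A gene with 0 reads had a fixed limit instead. No named gene at least 4-fold apart changed sign.

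For GlcNAc against sorbitol at 24 h, 463 genes were at least 4-fold lower, against 278 with the median gene set to 0, 299 with TMM scaling, 750 with TPM and 294 with the length trend removed. Removing that trend also sets the median gene to 0, which alone gives 278, so the move cannot be put down to length. A median gene at -0.43 enters this count, so a shift of scale moves it by construction. With 5 added in place of 1, the lower genes numbered 75 in place of 114 in glucose against sorbitol at 24 h, 111 in place of 179 at 24 h against 5 h in sorbitol, and 62 in place of 98 in glucose. A larger added value shrinks the ratios of genes near 0 by construction. Of the lists that stood apart and changed sign, hexose transporters in glucose against sorbitol at 5 h were at 0.014 with a mean of at least 10 RPKM (main value -0.41). Cytosolic ribosomal proteins at 24 h against 5 h in sorbitol were at 0.097 with the length trend removed (main value -0.01). By its percentile that list stood apart as higher (98.2), though 38 of 75 genes lay below the median gene. With random lists matched on length it lay inside the range (percentile 97.0). For these 2 lists the cause of the sign change was not tested. Random lists matched on length as well changed whether a list stood apart in at most 4 of 37 lists in a comparison. The libraries carry no replicate numbers to pair on, and a fit with time as a block was not made. Depth limits genes near 0 most: a floor of 3 reads is 0.239 to 0.263 RPKM for a gene of median length.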

Other observations

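Of the lists here, both were written after related genes had been seen, and the prediction for the phosphate list was written before that list was computed. The genes named from these lists were chosen after their values were seen.

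Phosphate genes other than PHO89 and the GIT family were examined as a list of 15, without PHO89, PHO8, PHO87 and GIT1 to GIT4, whose values had been seen. At 24 h its relative median was 0.83 in GlcNAc against sorbitol (percentile 98.0) and 1.56 in GlcNAc against glucose (percentile 100). At 5 h the percentiles were 82.0 and 96.8, and the list stood lower in glucose than in sorbitol (relative median -0.43, percentile 0.06). PHO84, a phosphate transporter gene, was at 1914 RPKM in GlcNAc at 24 h, 617 in sorbitol and 511 in glucose. The acid phosphatase genes PHO114 and PHO113 were at 193 and 255 RPKM in GlcNAc, 43.2 and 82.4 in sorbitol, and 36.3 and 87.0 in glucose. VTC3, of polyphosphate storage, and GDE1, a glycerophosphocholine phosphodiesterase, already stood at 588 and 234 RPKM in GlcNAc at 5 h, 209 and 83.6 in sorbitol, and 137 and 53.5 in glucose. PHM7 went against the list at 24 h, at 300.1 RPKM in GlcNAc, 584 in sorbitol and 504 in glucose, and so did PHO15 against glucose (15.3 and 88.2 RPKM). Outside the list, GIT3 was lower in GlcNAc at 5 h, at 50.8 RPKM against 292 in sorbitol and 297 in glucose.

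Genes of sulfate assimilation and methionine, without MET3, MET14 and SUL2, formed a list of 16. Most of them, MET15 and CYS3 included, also belong to the amino acid synthesis list, whose median had been seen, so these values test nothing further. The relative median was 1.26 in GlcNAc against sorbitol and 1.26 against glucose at 5 h (percentile 100 for both), and 1.59 and 1.06 at 24 h (percentiles 99.99 and 99.9). In glucose against sorbitol it was 0.01 at 5 h (percentile 45.2) and 0.63 at 24 h (percentile 99.8). The methionine permease gene MUP1 was at 352 RPKM in GlcNAc at 24 h, 17.1 in sorbitol and 15.5 in glucose, and MET28, a regulator gene, at 8296, 1237 and 1924 RPKM. CYS3 was at 670.1, 32.1 and 46.9 RPKM, and SAM2, the S-adenosylmethionine synthetase, at 409, 73.7 and 118. SAH1 went against the list at 24 h, at 120.2 RPKM in GlcNAc and 170.4 in sorbitol.

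A hypothesis that cells in GlcNAc for 24 h carry more transcripts of phosphate uptake and storage genes than cells in sorbitol or glucose passed its test, since the smaller of the 2 percentiles was 98.04. That test places the list relative to the median gene, so it cannot show more transcripts as such. Against sorbitol the list's own median log2 ratio was 0.41, and 3 of 15 genes were at least 2-fold higher. With TPM the median gene of that comparison lay at -0.80, so the list's own median depends on scaling. Against glucose its own median was 1.34, with 10 of 15 genes at least 2-fold higher. The result may hold for these libraries only, and the phosphate content of the media is not given in the sources used here.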
